A study of Sus scrofa with 8 samples.

How the data were processed

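Total RNA from frozen right ventricular free wall of 4 control and 4 pulmonary artery banded pigs was sequenced in bulk, with 1 library per animal. Per the labels' protocols, the tissue was pulverised and RNA was taken up in TRIzol and cleaned on spin columns with DNase. Per the file headers, the authors counted read pairs per gene with featureCounts 1.6.2, with a mapping quality of at least 10 and strand setting 2 (reverse-stranded), on Ensembl annotation release 106 of the pig genome build Sscrofa11.1. The counting command named 24 libraries, of which the 8 described here were analysed. Per the submitters' processing notes, Trimmomatic, HISAT2, Subread and DESeq2 were also used, and their versions and settings were not given in the sources used here. The deposited counts are whole numbers that were not normalised. A second deposited table holds the authors' own comparison, with a log2 fold change of control over banded and its standard error, a mean normalised signal, a Wald score, and a p-value with its adjusted p-value, under column names of DESeq2. The model and filters behind it were not given in the sources used here. The samples were grouped by their labels, which give no pairing and no sequencing batch, so neither could enter a fit.

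The count table held 31908 gene models, of which 16610 received a symbol. Symbols came from a reference table of gene names (15029), the authors' deposited table (713), the position of RefSeq genes on the same build (555, with a shared span of at least 0.8) and human orthologue names (313). There were 1027 models with exons of 2 or more RefSeq genes, whose reads cannot be separated, and 40 of them were among the genes that changed. Depth was 31033679 to 34183338 counts per library, and a count of 0 allowed at most 0.0878 to 0.0967 CPM (3 counts of the total, counting error only). No library was a copy of another. Within a group the Spearman correlation of libraries was 0.9551 to 0.9859 across genes, and the chi-square of a pair over its degrees of freedom was at least 27.5.

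Genes were kept by filterByExpr of edgeR (minimum count 10, minimum total 15), which left 13697, and the counts were scaled by TMM. Banded was compared with control by the quasi-likelihood F test of edgeR 4.0.16 with robust estimation in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was its size over the square root of F. CPM values are TMM-normalised and given as mean ± SD over 4 animals. On simulated counts of 13500 genes for this comparison, the test called 9.1% of 66 genes changed 1.5-fold, 68.7% of 67 genes changed 2-fold and 89.6% of 67 genes changed 4-fold, and 8 unchanged genes (6.7% of those called). Most simulated changes of 1.5-fold were therefore not detected with 4 animals per group. Only 200 genes changed in the simulation, fewer than the 954 called in the data. With fewer changed genes the adjusted threshold is stricter, so recovery in the data may be higher.

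Before the data were examined, 44 gene lists were fixed, 27 on the biology of the right ventricle and 17 on other tissue, cell types and handling, with 1226 entries of which 1125 matched a gene. The 43 lists with at least 5 tested members were tested with camera of limma 3.58.1 (preset correlation 0.01, two-sided), adjusted over the 43. An estimated correlation, fry and an exact two-sided permutation test of the mean log2 CPM of the members (prior count 2) stood beside it. The permutation test has 70 assignments and a smallest possible p of 0.0286, reached by 9 lists, for which the adjusted p was 0.137. With the estimated correlation 0 of the 43 lists passed in camera (2 at an unadjusted p under 0.05), and fry passed 1 (8 at an unadjusted p under 0.05).

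The genes to name were also set beforehand. They were the 10 largest rises and 10 deepest falls among genes with an adjusted p under 0.05, a symbol, a mean of at least 1 CPM and groups that did not overlap. For each of the 27 lists, the 2 called members with the smallest adjusted p and the most abundant member were added, for each of the 17 up to 2 called members, and always NPPA, NPPB, MYH6, MYH7, ATP2A2, COL1A1, COL3A1, POSTN, CD36, CPT1B, PPARGC1A, GPX4, TFRC and PDGFRB. Leaving out a gene that is not reported here, the rule gave 109 genes, 79 of them called, of which the text prints a part. NPPA and NPPB share 1 gene model, as do MYH6 and MYH7.

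Alternatives were DESeq2 1.42.0, limma-voom with quality weights, median-of-ratios, upper-quartile and library size scaling, no filter, a filter of 50 counts in 4 libraries, no robust estimation, a test against a 1.5-fold change, 1 surrogate variable (sva 3.50.0), leaving out mitochondrial-genome genes, and leaving out each library in turn. One further alternative, without mitochondrial-genome genes and a gene model on chromosome 9, was chosen after seeing the data. A fit of banded against control 4 alone was run once and dropped, because it picked a control by its measured values, and no result from it is used. Overlap with the authors' deposited table is given with 95% Wilson intervals. Tables and exact tests used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.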

Results

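Bulk RNA sequencing measured gene expression in the right ventricular free wall of 8 Yorkshire cross pigs. In 4 castrated male piglets the main pulmonary artery had been banded, a constriction that raises the pressure against which the right ventricle ejects. Another 4 pigs of similar age and weight, whose sex the labels do not state, served as controls. Per the labels, surgery was done at 4.5 ± 0.6 weeks of age and 6.4 ± 1.3 kg, and the band was tightened until right ventricular systolic pressure peaked at about 30 to 40 mmHg. Controls were housed for 8 weeks, and their labels give the treatment as none. The time from banding to tissue collection was not given in the sources used here, and no sham operation is named. Each library is a separate animal. The deposited count table held 32741406, 31033679, 31858923 and 34183338 counts in controls 1 to 4. Banded 1 to 4 held 34008264, 32630472, 34169120 and 31400659 counts. Transcripts of the mitochondrial genome took 38.3% ± 3.9 of the counts in controls and 36.3% ± 4.2 in banded animals (SD, n = 4 each). Of the 31908 gene models in the table, 11414 had 0 counts in all libraries and 13697 entered the test.

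The comparison asked which genes differ in the right ventricle of banded pigs, in a series on right ventricular failure. The right ventricle of banded pigs held far more TNNT1, the slow skeletal isoform of troponin T, than that of controls (1183 ± 392 against 36.4 ± 7.87 CPM, SD, n = 4), a rise of 5.02 ± 0.29 on the log2 scale (SE) with an edgeR quasi-likelihood adjusted p of 2.42e-05. FRZB, a secreted Wnt antagonist, rose from 14.2 ± 5.97 to 718 ± 273 CPM (log2 fold change 5.66 ± 0.44, adjusted p = 0.000249). ACE, the angiotensin-converting enzyme, fell from 77.8 ± 9.27 to 30.0 ± 4.48 CPM (log2 fold change -1.38 ± 0.14, adjusted p = 0.00047). ACTC1, the cardiac alpha-actin gene, fell from 4790 ± 817 to 1723 ± 292 CPM (log2 fold change -1.47 ± 0.18, adjusted p = 0.00133). In total, 954 of 13697 genes changed at an adjusted p under 0.05, of which 475 were higher and 479 lower in banded pigs, and 446 changed by 2-fold or more (255 higher and 191 lower). For 923 of the 954 genes the banded and control values did not overlap. Over all tested genes the groups did not overlap in 15.9%, against 2.86% by chance with 4 against 4. The first principal component took 44.3% of the variance of the 500 most variable genes and separated the groups. The count of 954 depended on controls 1 to 3: it was 399, 415 and 409 without control 1, 2 or 3, but 786 without control 4. Without 1 banded library it was 725 to 962. Controls 1 to 3 were closer to each other (Spearman correlation 0.9834 to 0.9859) than to control 4 (0.9751 to 0.9798). The labels give no sequencing batch or maternal line, and they number the libraries and animals of the groups in separate blocks. A difference in batch or maternal line between the groups therefore cannot be told apart from banding. The same holds for sex, stated only for banded pigs, and for the surgery itself, as no sham operation is named. DESeq2 called 1631 genes, and a test against a 1.5-fold change called 148. Scaling by library size alone called 303 higher and 508 lower (37.4% higher, against 49.8%), as it moved the median log2 fold change of all genes by -0.10.

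**Figure D1:**
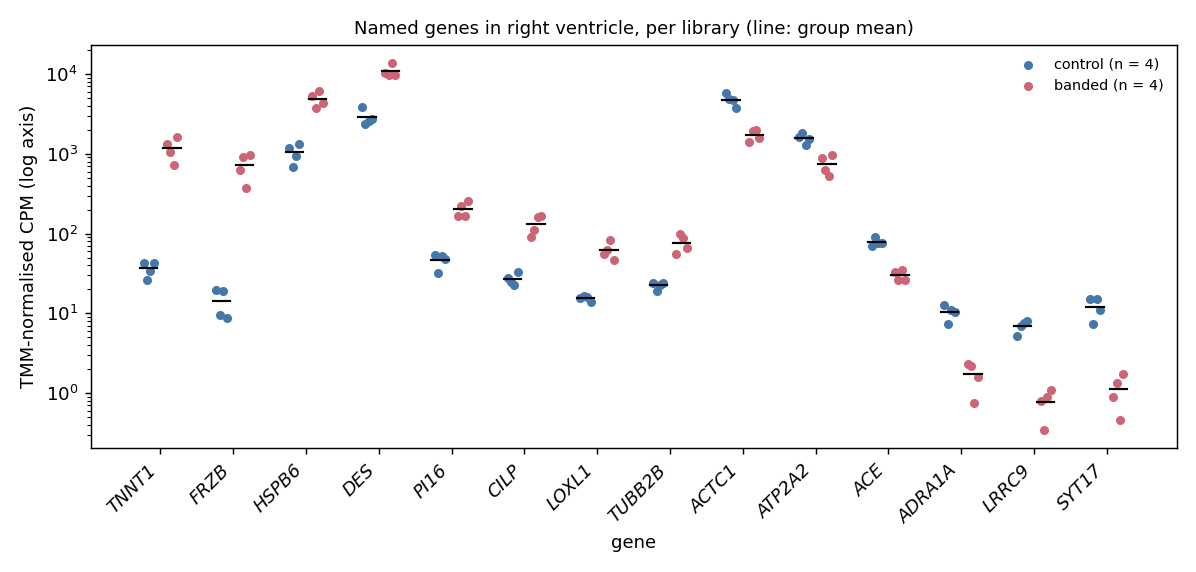
TMM-normalised CPM (counts scaled by library, log axis) of 14 named genes in each right ventricle library, controls in blue and banded in red (n = 4 each), with a line at each group mean. For each of these genes every banded value lies on one side of every control value, as for TNNT1, with means of 36.4 and 1183 CPM.

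The 10 genes with the largest rises under the rule fixed beforehand also included DUSP13, a dual-specificity phosphatase (0.453 ± 0.175 to 8.10 ± 2.06 CPM, log2 fold change 4.15 ± 0.34, adjusted p = 0.000163), WWC1, a scaffold of the Hippo pathway (log2 fold change 4.27 ± 0.56, adjusted p = 0.00169), and KRT80, a keratin (3.75 ± 1.40 to 69.8 ± 44.2 CPM, log2 fold change 4.22 ± 0.61, adjusted p = 0.00927). CP, the ferroxidase ceruloplasmin (log2 fold change 4.03 ± 0.76, adjusted p = 0.0112), and KRT18, a keratin of simple epithelia (3.70 ± 0.69, adjusted p = 0.0103), rose from a control mean under 1 CPM. Controls held 0 to 0.232 CPM of CP and 0.0587 to 0.264 CPM of KRT18, so the sizes of these rises are imprecise. The remaining rises, of ANKRD2, a stretch-responsive muscle ankyrin repeat gene (6.95 ± 1.57), RAB3B, a small GTPase of exocytosis (6.40 ± 1.18), and TNFSF18, a ligand of the tumour necrosis factor family (3.89 ± 0.89), varied more between animals. ANKRD2 reached 198 CPM in banded 3 and 6.43 to 19.2 CPM in the other banded libraries, TNFSF18 8.04 CPM against 0.938 to 1.33, and without banded 3 the log2 fold changes were 4.76 and 2.49. For ANKRD2 it was 7.60 without control 2. RAB3B reached 53.8 CPM in banded 4 against 2.01 to 14.3 CPM, with a log2 fold change of 5.18 without it. For TNFSF18 (0.0293 to 0.281 CPM), RAB3B (0.147 to 0.377 CPM) and ANKRD2 (0.0843 to 0.986 CPM) too the controls were near 0. The log2 fold change of KRT18 was 2.91 without banded 2. The calls of ANKRD2, RAB3B and TNFSF18 ended without any 1 of the controls, with adjusted p of 0.104 to 0.143, 0.0618 to 0.0872 and 0.0656 to 0.101. The call of ANKRD2 also ended without banded 1 (0.0577) or banded 2 (0.0626). Limma-voom with quality weights did not call ANKRD2 (0.128) or RAB3B (0.109), and neither library size alone (0.0596) nor testing without a filter (0.0779) called ANKRD2.

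Among the 10 deepest falls, SYT17, a synaptotagmin, fell from 12.1 ± 3.73 to 1.11 ± 0.55 CPM (log2 fold change -3.45 ± 0.39, adjusted p = 0.000784). LRRC9, a leucine-rich repeat gene, fell from 6.87 ± 1.18 to 0.776 ± 0.313 CPM (-3.15 ± 0.33, adjusted p = 0.00047). The log2 fold change was -4.43 ± 0.67 for the cell adhesion gene CDH9 (adjusted p = 0.00355), -4.94 ± 0.76 for FAM216B (0.00571) and -2.94 ± 0.55 for LYPD6B (0.0108). It was -4.76 ± 0.88 for GALNT14, an enzyme of mucin-type glycosylation whose gene model also covers exons of CAPN13 (0.0103), and -3.08 ± 0.61 for S100A16, a calcium-binding protein gene (0.0139). S100A16 was at 0.528 CPM in control 4 and at 2.73 to 3.32 CPM in controls 1 to 3. Without 1 banded library the log2 fold change was -5.19 for CDH9 and -3.53 for LYPD6B without banded 4, -6.35 for GALNT14 without banded 3 and -4.37 for CDH18 without banded 2. The sizes of these falls are imprecise, as the banded libraries held 0 to 0.209 CPM of CDH9, 0 to 0.216 CPM of GALNT14, 0 to 0.278 CPM of FAM216B, 0 to 0.54 CPM of CDH18 and 0.126 to 0.73 CPM of LYPD6B. A count of 0 allows up to 0.0878 to 0.0967 CPM. Limma-voom with quality weights did not call FAM216B (adjusted p = 0.0634), S100A16 (0.0605) or CDH18 (0.0689). KCNJ5, a subunit of the acetylcholine-activated potassium channel, was at 75.3 ± 9.85 CPM in controls and at 3.90 to 5.41 CPM in 3 banded libraries, but at 24.5 CPM in banded 1 (log2 fold change -2.99 ± 0.65, adjusted p = 0.0389, and -4.07 without banded 1). Its call ended without any 1 control (adjusted p 0.0726 to 0.0979) and without banded 2 (0.0735), banded 3 (0.0999) or banded 4 (0.0709), without a filter on low counts (0.0806) and with 1 surrogate variable (0.0816). CDH18 (log2 fold change -3.46 ± 0.83) lost its call without control 1 (0.0725), control 2 (0.0866), control 3 (0.103), banded 1 (0.0749) or banded 4 (0.0696). PEBP4 (-2.92 ± 0.62) lost it without control 1 (0.0572), control 3 (0.0672) or banded 2 (0.0556).

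Genes of the cardiomyocyte stretch and fetal program were higher as a list in camera. Of 19 tested members 7 were called higher and 0 lower (11 and 1 adjusted over the list alone). The median log2 fold change was 1.40, and camera with its preset correlation gave an adjusted p of 1.88e-09. With an estimated correlation the adjusted p was 0.791, and it was 0.188 in fry. DES, the intermediate filament of muscle, rose from 2899 ± 649 to 10960 ± 1911 CPM (log2 fold change 1.92 ± 0.20, adjusted p = 0.00047). FHL1, a LIM-domain sarcomere gene, rose from 200 ± 19.4 to 837 ± 389 CPM (2.06 ± 0.27, adjusted p = 0.00188). All 4 banded libraries scored above all controls on this list. Banded 3 scored highest, 2.2 above the control mean on the log2 scale against 0.546 to 0.951 in the other banded libraries. The natriuretic peptide genes NPPA and NPPB lie in 1 gene model on chromosome 6 (71919495 to 71932254, Sscrofa11.1), so their reads cannot be separated. That model was at 35.8 ± 22.6 CPM in controls and 386 ± 399 CPM in banded animals, higher in 4 of 4 banded libraries than in every control, and missed the threshold (log2 fold change 3.43 ± 0.85, adjusted p = 0.0603). Banded 3 held 975 CPM of it and the other banded libraries 110 to 291, and without banded 3 the log2 fold change was 2.41 (adjusted p = 0.0639). DESeq2 called it (adjusted p = 0.00049), as did limma-voom (0.0474) and edgeR without robust estimation (0.0178).

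Adult ventricular sarcomere genes went both ways, with 2 called higher and 2 lower of 22 (5 and 5 adjusted over the list alone), and the list was not called (camera adjusted p = 0.978, with a positive median, a negative mean and a downward test). Besides ACTC1, MYOM3, an M-band gene, fell (260 ± 19.1 to 159 ± 14.2 CPM, log2 fold change -0.71 ± 0.13, adjusted p = 0.00824). The gene model named MYH6 on chromosome 7 (75650445 to 75709232) also covers exons of MYH7 and CMTM5, so a shift between the cardiac myosin heavy chains could not be measured. The model was at 17720 ± 3231 CPM in controls and 19590 ± 2852 CPM in banded animals (adjusted p = 0.679). Heat-shock genes (2 higher and 0 lower of 20, over all genes and adjusted over the list alone) rose as a list in camera (adjusted p = 0.0356, but 0.791 as the adjusted p with an estimated correlation). The small heat-shock protein genes HSPB6 (1040 ± 279 to 4851 ± 1056 CPM, log2 fold change 2.22 ± 0.24, adjusted p = 0.00047) and HSPB7 (670 ± 28.8 to 1579 ± 555 CPM, adjusted p = 0.00827), both abundant in striated muscle, were the called members. The heat-shock list rested on banded 3, without which its adjusted p was 0.433, and its call also ended without control 1 (0.0565), control 2 (0.0527) or control 3 (0.066). Tubulin and microtubule-associated genes (2 higher and 0 lower of 22, 5 and 0 adjusted over the list alone) had a camera adjusted p of 0.0356 and an adjusted p of 0.791 with an estimated correlation. TUBB2B, a beta-tubulin, rose from 22.4 ± 2.38 to 76.2 ± 19.8 CPM (log2 fold change 1.77 ± 0.19, adjusted p = 0.00047), while the most abundant member, TUBB, was at 413 ± 59.7 and 653 ± 206 CPM (adjusted p = 0.095). TUBB was called higher by DESeq2 (0.0304), by limma-voom (0.0412) and without banded 4 (0.0273). This list lost its call without banded 3 (0.16), control 2 (0.067) or control 3 (0.0537).

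**Figure D2:**
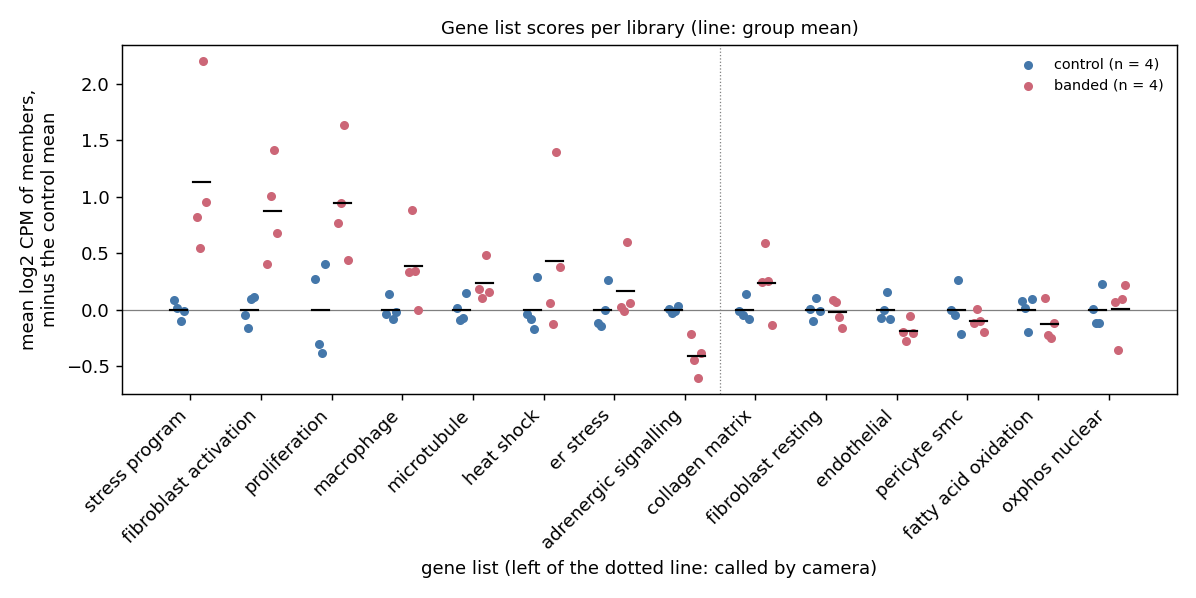
Score of 14 gene lists in each library, as the mean log2 CPM of the members minus the control mean, controls in blue and banded in red (n = 4 each), with a line at each group mean; lists left of the dotted line were called by camera with its preset correlation. Banded 3 has the highest stress program score, at 2.2, and all 4 banded libraries lie below the controls in adrenergic signalling.

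Genes of adrenergic, angiotensin and endothelin signalling were lower as a list in camera. Of 33 tested members 7 were called lower and 2 higher (10 and 2 adjusted over the list alone), and all 4 banded libraries scored below all controls. The camera adjusted p was 0.00113. The adjusted p was 0.185 with an estimated correlation and 0.00318 in fry, which asks only whether the members move one way on balance. Besides ACE, ADRA1A, the alpha-1A adrenergic receptor, fell from 10.3 ± 2.22 to 1.72 ± 0.72 CPM (log2 fold change -2.58 ± 0.33, adjusted p = 0.00143). ADCY6, a cardiac adenylyl cyclase, was at 437 ± 80.6 and 200 ± 70.4 CPM (adjusted p = 0.0265), a call lost without control 1 (0.052), control 2 (0.0822), control 3 (0.07), banded 2 (0.0502) or banded 4 (0.0566). Calcium cycling genes were called in both directions (2 higher and 4 lower of 23, 4 and 7 adjusted over the list alone, camera adjusted p = 0.223). ATP2A2, the calcium pump of the sarcoplasmic reticulum, fell from 1573 ± 226 to 755 ± 212 CPM (log2 fold change -1.06 ± 0.21, adjusted p = 0.0141, and 0.0521 without control 2). CASQ2, which binds calcium in that store, was higher (524 ± 81.6 to 844 ± 72.2 CPM, adjusted p = 0.0224), a call lost without control 2 (0.0692), control 3 (0.0835) or banded 1 (0.0551), and with library size alone (0.0511). Potassium, sodium and gap-junction channel genes had 1 member called higher and 2 lower of 21 (1 and 4 adjusted over the list alone). The list was not called (camera adjusted p = 0.134) except without banded 1 (0.0066), although all 4 banded libraries scored below all controls. KCNE1, a potassium channel subunit, rose from 21.8 ± 4.11 to 40.3 ± 7.16 CPM (adjusted p = 0.0135).

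Activated fibroblast and matricellular genes were higher as a list in camera. Of 36 tested members 10 were called higher and 1 lower (15 and 2 adjusted over the list alone). The median log2 fold change was 0.71 and the camera adjusted p was 2.59e-12. With an estimated correlation the adjusted p was 0.654. CILP, a matrix protein gene of fibroblasts, rose from 27.0 ± 4.37 to 132 ± 37.7 CPM (log2 fold change 2.29 ± 0.21, adjusted p = 0.000249). LOXL1, a collagen and elastin crosslinking enzyme, rose from 15.5 ± 1.02 to 61.6 ± 15.8 CPM (1.99 ± 0.17, adjusted p = 0.000184). FN1, another member, was higher (log2 fold change 1.11, adjusted p = 0.0205). Its call ended without any 1 control (0.0524 to 0.066) and with library size alone (0.0628). POSTN, a marker of activated fibroblasts, was at 168 ± 60.1 and 290 ± 156 CPM and was not called (adjusted p = 0.313). The main fibrillar collagens were not called either: COL1A1 was at 1594 ± 213 and 1895 ± 621 CPM (adjusted p = 0.567) and COL3A1 at 5878 ± 813 and 4974 ± 1238 CPM (adjusted p = 0.508). Among collagen and matrix genes as a list, 6 were called higher and 1 lower of 35 (7 and 1 adjusted over the list alone). BGN, the proteoglycan biglycan, rose from 65.8 ± 19.4 to 221 ± 65.9 CPM (adjusted p = 0.00329) and COL8A1, a short-chain collagen, from 51.7 ± 12.7 to 190 ± 65.6 CPM (adjusted p = 0.00188). That list was not called (camera adjusted p = 0.0939) unless control 3 (0.0275) or banded 4 (0.00127) was left out. Identity markers of fibroblasts moved apart, 3 higher and 3 lower of 19 (5 and 5 adjusted over the list alone, camera adjusted p = 0.976, where the median and the mean were negative and the test was not). PI16, a marker of adventitial fibroblasts, rose from 46.6 ± 10.0 to 204 ± 45.5 CPM (log2 fold change 2.13 ± 0.21, adjusted p = 0.000315), and THY1 from 169 ± 37.2 to 348 ± 48.9 CPM (adjusted p = 0.00809).

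Cell-cycle genes rose as a list in camera. Of 31 tested members 30 had a positive log2 fold change, 8 were called higher and 0 lower (24 and 0 adjusted over the list alone). The median log2 fold change was 1.08 and the camera adjusted p was 7.61e-11. With an estimated correlation the adjusted p was 0.791. DLGAP5, a mitotic spindle gene, was higher (1.68 ± 0.75 to 5.15 ± 1.84 CPM, adjusted p = 0.0228), as was CDKN1A, which encodes an inhibitor of the cell cycle (50.6 ± 12.1 to 98.0 ± 18.5 CPM, adjusted p = 0.0158). DLGAP5 lost its call without control 1 (0.0561), control 2 (0.0776) or control 3 (0.0696), and CDKN1A without control 3 (0.0564). The most abundant member, CCND1, was at 78.9 ± 13.1 and 92.9 ± 31.0 CPM (adjusted p = 0.544). Scores against the control mean were 0.77, 0.94, 1.64 and 0.44 in banded 1 to 4, and the highest control score was 0.41.

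Macrophage and monocyte markers rose as a list in camera (2 called higher and 0 lower of 30, over all genes and adjusted over the list alone). The camera adjusted p was 0.00205 with the preset correlation and 0.791 with the estimated one, which was 0.404. The adjusted p was 0.219 in fry, and the exact permutation p was 0.0571. The scores were 0.34, 0.88, 0.35 and 0.0021 above the control mean in banded 1 to 4, and without banded 2 the list was not called (0.0978). F13A1, a marker of resident macrophages, was higher (12.3 ± 2.27 to 25.4 ± 8.90 CPM, adjusted p = 0.0214), a call lost without control 1 (0.0712), control 3 (0.0747) or control 4 (0.0523), and with library size alone (0.0605). The most abundant member, C1QB, was at 169 ± 43.1 and 266 ± 38.6 CPM (adjusted p = 0.0639). It was called higher by DESeq2 (0.0171), by limma-voom (0.0269), without a filter on low counts (0.0417) and without control 4 (0.034). T, NK, B and plasma cell markers had 1 member called higher and 1 lower of 22, over all genes and adjusted over the list alone (camera adjusted p = 0.351). The CCL5 level was 13.4 ± 2.58 and 12.3 ± 5.11 CPM (adjusted p = 0.856). Cytokine and adhesion genes (1 higher and 0 lower of 34 on both adjustments, camera adjusted p = 0.454) and antigen-presentation genes (0 of 20 on both and in DESeq2 and limma-voom, 1 at an unadjusted p under 0.05, 0.59) were not called as lists. Interferon-response genes (0 higher and 1 lower of 31, and 0 adjusted over the list alone, 0.219) were not called as a list either, except without banded 2 (0.0358).

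Of the nuclear genes of the respiratory chain, edgeR called 0 of 68, 0 also adjusted over the list alone, and the camera adjusted p was 0.927. At an unadjusted p under 0.05 there were 3, and DESeq2 and limma-voom called 0. Fatty acid uptake and oxidation genes had 0 members called higher and 3 lower of 30 (0 and 5 adjusted over the list alone), and the list was not called (0.198). ACAA2, the last enzyme of mitochondrial beta-oxidation, fell from 345 ± 47.0 to 203 ± 30.4 CPM (log2 fold change -0.77 ± 0.16, adjusted p = 0.0157, and 0.0561 without control 1). CD36, a fatty acid transporter, was at 429 ± 33.2 and 312 ± 80.3 CPM (adjusted p = 0.168). CPT1B, the muscle carnitine palmitoyltransferase, whose gene model also covers exons of CHKB, was at 233 ± 33.3 and 192 ± 16.3 CPM (0.26). FABP3 was at 742 ± 69.6 and 789 ± 279 CPM (0.853). PPARGC1A, a coactivator of mitochondrial gene expression, was at 90.9 ± 40.1 and 42.7 ± 10.5 CPM (adjusted p = 0.0634), and DESeq2 called it lower (0.00274), as did edgeR without control 4 (0.0249). Its list of metabolic regulators had 0 of 25 members called by edgeR (2 higher and 4 lower adjusted over the list alone and in DESeq2, 9 at an unadjusted p under 0.05, camera adjusted p = 0.198). Limma-voom called 0 higher and 2 lower. Tricarboxylic acid cycle genes had 0 members called higher and 3 lower of 30 on both adjustments (camera adjusted p = 0.0603). Among them was PDP1, the pyruvate dehydrogenase phosphatase (35.6 ± 2.34 to 19.8 ± 3.50 CPM, adjusted p = 0.00688). Genes of ketone and branched-chain amino acid catabolism had 0 higher and 1 lower of 22 (0 and 3 adjusted over the list alone, camera adjusted p = 0.0603), PPM1K, the phosphatase that activates branched-chain keto acid dehydrogenase (137 ± 27.3 to 55.3 ± 14.9 CPM, adjusted p = 0.00607). Both lists were called lower without control 3 (both 0.0237), without banded 4 (0.00921 and 0.00245) and with library size alone (0.00963 and 0.0187), and the first also without banded 1 (0.022). Glucose uptake and glycolysis genes had 5 members called higher and 0 lower of 25 (7 and 1 adjusted over the list alone), with a camera adjusted p of 0.115 for the list, and of 0.0146 without banded 2. GYS1, glycogen synthase, was higher (148 ± 20.6 to 234 ± 26.8 CPM, adjusted p = 0.0209), a call lost without control 2 (0.0525) or control 3 (0.0799) and with library size alone (0.0577). GAPDH was at 6551 ± 1379 and 7084 ± 1755 CPM (0.802).

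Iron handling and ferroptosis-related genes were called in both directions, 4 higher and 2 lower of 39 (8 and 5 adjusted over the list alone, camera adjusted p = 0.24). All 4 banded libraries scored above all controls on this list, by 0.235 on average (exact p = 0.0286, adjusted 0.137). GCLM, a subunit of the enzyme that starts glutathione synthesis, rose from 9.46 ± 0.83 to 19.5 ± 1.94 CPM (adjusted p = 0.00171). ALOX15, a lipoxygenase whose model also covers ALOX12 exons, rose from 2.15 ± 0.45 to 11.9 ± 6.04 CPM (adjusted p = 0.00678). FTH1, a ferritin gene, was higher (log2 fold change 0.87, adjusted p = 0.0262). Its call ended without control 1 (0.0768), control 2 (0.092), control 3 (0.0802), banded 3 (0.0502) or banded 4 (0.051). GPX4, which reduces lipid peroxides, was at 258 ± 43.4 and 305 ± 90.4 CPM (adjusted p = 0.525), and TFRC, the transferrin receptor, at 117 ± 16.7 and 85.8 ± 12.2 CPM (0.0946, and 0.0388 in limma-voom). Antioxidant genes had 1 member called higher and 0 lower of 37 on both adjustments (camera adjusted p = 0.115), MGST3 (140 ± 20.3 to 266 ± 33.6 CPM, adjusted p = 0.00571). Here too all 4 banded libraries scored above all controls, by 0.202 (exact p = 0.0286, adjusted 0.137). Unfolded-protein-response genes had 2 members called higher and 1 lower of 33 on both adjustments, with a camera adjusted p of 0.0468 and an adjusted p of 0.791 with an estimated correlation. The called members moved apart. DNAJB9, a chaperone of the endoplasmic reticulum, rose from 9.71 ± 0.42 to 17.1 ± 1.05 CPM (adjusted p = 0.00453). DDIT3, the stress transcription factor CHOP, fell from 3.20 ± 0.77 to 0.832 ± 0.189 CPM (adjusted p = 0.00571). This list rested on banded 3 (adjusted p 0.315 without it) and also lost its call without control 1 (0.098), control 2 (0.067) or control 3 (0.0644), and with library size alone (0.0545). Autophagy and muscle ubiquitin ligase genes had 2 members called higher and 2 lower of 33 on both adjustments (camera adjusted p = 0.183, and 0.0366 without banded 1). ASB15, a muscle ubiquitin ligase component, fell from 137 ± 8.00 to 46.4 ± 12.5 CPM (log2 fold change -1.57 ± 0.18, adjusted p = 0.000784), and ASB14 from 7.15 ± 2.67 to 1.26 ± 0.66 CPM (adjusted p = 0.00863).

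Endothelial markers had 1 member called higher and 3 lower of 34 (2 and 4 adjusted over the list alone, camera adjusted p = 0.115). SOX18, an endothelial transcription factor, fell from 18.1 ± 1.42 to 5.53 ± 2.11 CPM (log2 fold change -1.71 ± 0.25, adjusted p = 0.00266). PALMD rose from 143 ± 6.02 to 305 ± 61.9 CPM (adjusted p = 0.00247), and AQP1 was at 334 ± 43.0 and 302 ± 17.3 CPM (0.564). Hypoxia-response and angiogenic genes had 2 members called higher and 5 lower of 35 (5 and 7 adjusted over the list alone, camera adjusted p = 0.198, and 0.036 without banded 4). EGLN3, an oxygen-sensing hydroxylase, rose from 43.3 ± 5.62 to 82.3 ± 12.1 CPM (adjusted p = 0.00443). PFKFB4, a regulator of glycolysis, fell from 8.89 ± 1.19 to 4.48 ± 0.44 CPM (adjusted p = 0.009). Pericyte and smooth muscle markers had 0 of 24 called by edgeR (2 higher and 2 lower adjusted over the list alone, 10 at an unadjusted p under 0.05, camera adjusted p = 0.219), while DESeq2 called 2 higher and 3 lower and limma-voom 1 and 1. PDGFRB was at 77.0 ± 8.98 and 57.5 ± 18.7 CPM (adjusted p = 0.262). CNN1, a calponin, was at 84.2 ± 23.3 and 532 ± 550 CPM (adjusted p = 0.0639), with 1348 CPM in banded 3 and 156 to 350 CPM in the other banded libraries, and was called higher without banded 3 (log2 fold change 1.62 against 2.66, adjusted p = 0.013) or banded 4 (0.0364). DESeq2 (0.00257), limma-voom (0.0329), edgeR without robust estimation (0.0242) and edgeR with 1 surrogate variable (0.0207) also called CNN1 higher.

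Markers of tissue other than ventricular muscle were not called as lists. Epicardial markers had 1 member called higher and 1 lower of 7 (2 and 1 adjusted over the list alone, camera adjusted p = 0.268), yet all 4 banded libraries scored above all controls, by 1.03 on the log2 scale on average. The largest changes among the 7 were of the keratins KRT18 and KRT8 (7.47 ± 7.19 and 63.2 ± 33.1 CPM, log2 fold change 3.08, adjusted p = 0.0787). Adipocyte markers (0 of 11 called on both adjustments, camera adjusted p = 0.404) scored 2.47 above the control mean in banded 1 and -1.49 to -0.168 in the other banded libraries. Erythroid markers (0 of 6 on both, 0.404) scored 2.30 in banded 4 and -0.186 to 0.0933 in the other banded libraries. Neutrophil and mast cell markers (0 of 8 on both, 0.918) were not called. Nor were atrial markers (0 higher and 1 lower of 7, 1 and 1 adjusted over the list alone, 0.65, where the mean was positive and the median and the test were not), Schwann cell and neuronal markers (1 and 0 of 14, 1 and 1 adjusted over the list alone, 0.906, where the mean was positive and the median and the test were not), lymphatic and endocardial markers (0 and 1 of 11 on both, 0.147) or fast skeletal muscle markers (1 higher and 1 lower of 6, 2 and 1 adjusted over the list alone, 0.268). On the lymphatic and endocardial list all 4 banded libraries scored below all controls (difference -0.37, exact p = 0.0286, adjusted 0.137). Of the lists that respond to handling, hour or hormones, immediate-early genes (0 of 21 on both adjustments, 0.254, and 0.0412 without banded 3), clock genes (0 of 17 on both, 0.196) and glucocorticoid-responsive genes (0 of 12 on both, 0.28) were not called. Ribosomal protein genes (0 of 46 on both, 0.254, and 0.0047 without control 4) and complement genes (1 higher and 1 lower of 14 on both adjustments, 0.198, and 0.036 without banded 4) were not called either. In the context lists with 0 members called by edgeR, the number at an unadjusted p under 0.05 was 1 for adipocyte, 1 for neutrophil and mast cell, 0 for erythroid, 4 for immediate-early, 3 for clock, 4 for glucocorticoid and 1 for ribosomal protein genes. DESeq2 called 1 adipocyte gene higher, 4 immediate-early genes lower and 2 glucocorticoid-responsive genes higher. Limma-voom called 1 adipocyte gene higher and 1 immediate-early gene lower, and both called 0 in the other 4 lists. In the histone and long nuclear RNA list too few members were measured for a test, and H2AC6, a histone gene, was higher (0.495 ± 0.435 to 3.77 ± 1.53 CPM, log2 fold change 2.94, adjusted p = 0.0124, and 3.70 without control 4).

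Protein genes of the mitochondrial genome were not called as a list (camera adjusted p = 0.918, 1 lower and 0 higher of 13 on both adjustments, where the mean was positive and the median and the test were not). ND6, the complex I gene on the opposite strand, was lower (186 ± 20.2 to 112 ± 23.4 CPM, adjusted p = 0.0224), a call lost without control 1 (0.0592), control 2 (0.0754), control 3 (0.0771) or banded 1 (0.0537). Controls 1 to 3 held 46, 40 and 40 counts of ATP8, control 4 held 94998 and the banded libraries 60815 to 85243. ND1 was at 141124 to 147921 counts in controls 1 to 3, 976911 in control 4 and 601236 to 815220 in the banded libraries. Neither gene was called (adjusted p = 0.748 and 0.516). Without control 4 the list was called higher (2.61e-07), but all controls in that fit held the low ATP8 and ND1 counts. Whether these genes alone gave that call was not tested. A gene model without a symbol on chromosome 9 (4700784 to 4700878) ran the other way, with 143485 to 171433 counts in controls 1 to 3 and 623 to 1023 in the other 5 libraries, and was among the 479 genes called lower (adjusted p = 0.0316).

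**Figure D3:**
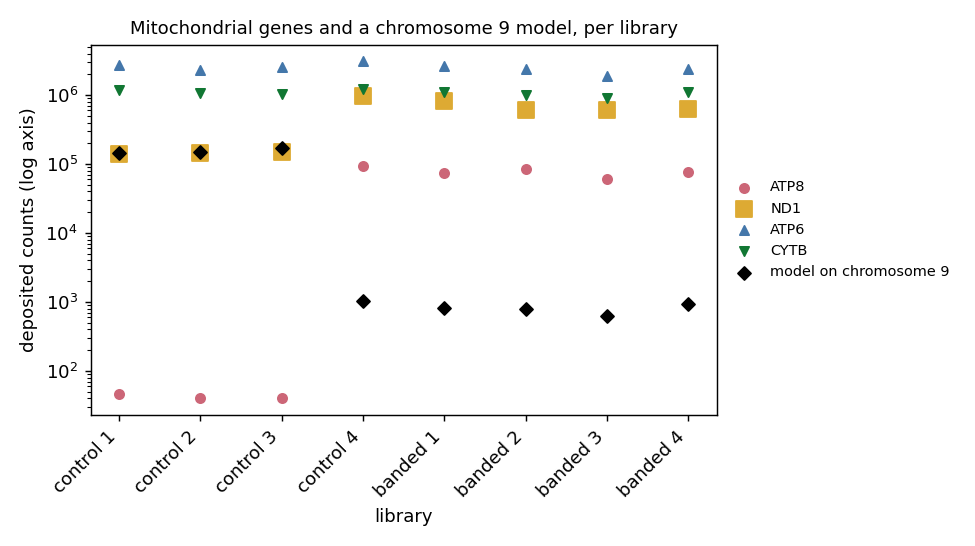
Deposited counts (log axis) of 4 mitochondrial genes and of the gene model on chromosome 9, in each of the 8 libraries. ATP8 lies at 40 to 46 counts in controls 1 to 3 and at 60815 to 94998 in the other 5 libraries, the model on chromosome 9 goes the other way, and ATP6 and CYTB stay within 1917857 to 3077361 and 904779 to 1207097 counts.

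The authors' deposited table of the same comparison lists 1489 genes at its adjusted p under 0.05, 706 higher and 783 lower in banded animals after its sign, control over banded, is turned. Among the 12872 genes tested in both, 897 of the 906 called here were called there with the same sign (99.0%, 95% Wilson interval 98.1 to 99.5) and 0 with the opposite sign, and these were 61.9% (59.3 to 64.3) of the 1450 called there. The fold changes had a Pearson r of 0.942 across these genes, which are not independent replicates, and both analyses rest on the same 8 libraries.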

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

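The splits of the libraries and the tests of the patterns below were chosen after the results were seen, except the gene length and slope tests of banded 3. In 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, edgeR called 954 genes, and the highest count in any other split was 1. Every other split mixes banded and control libraries, so any difference between the groups widens its spread and lowers its count. A share of 1 in 35 is the smallest this design can give, so chance is unlikely but not excluded. The splits cannot separate banding from anything else that differs between the groups. A library was far from the other 3 of its group in 20 of 312 groups of values, against 15.6 by chance, which marks about 1 in 20 groups (Dixon's test of the gap to the nearest library over the group's range). These were control 4 in 6 groups, banded 3 in 5, banded 2 in 3, control 3 in 2, and controls 1 and 2 and banded 1 and 4 in 1 each.

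In banded 3 the unfolded-protein-response score was 0.604 against -0.00649 to 0.0581 in the other banded libraries (gap over range 0.894), ANKRD2 was at 198 against 6.43 to 19.2 CPM (0.933), CNN1 at 1350 against 156 to 349 CPM (0.838), DES at 13800 against 9830 to 10400 CPM (0.861) and TNFSF18 at 8.04 against 0.938 to 1.33 CPM (0.945). Banded 2 had BGN at 318 against 173 to 196 CPM (0.844), KRT18 at 4.95 against 1.01 to 1.61 CPM (0.848) and MDH2 at 810 against 1110 to 1140 CPM (0.914). Banded 1 had KCNJ5 at 24.5 against 3.9 to 5.41 CPM (0.926), and banded 4 had an erythroid score of 2.3 against -0.186 to 0.0933 (0.888). In control 4 the mitochondrial-genome score was 1.09 against -0.423 to -0.268 in the other controls (0.898), the complement score -0.31 against 0.0724 to 0.136 (0.858), CCND1 98.5 against 70.9 to 73.8 CPM (0.892), GPX4 323 against 233 to 241 CPM (0.913), LPL 452 against 326 to 334 CPM (0.934) and MAP4 281 against 356 to 357 CPM (0.994). Control 3 had AQP1 at 398 against 305 to 317 CPM (0.869) and GALNT14 at 0.562 against 2.31 to 2.61 CPM (0.854). Control 1 had FHL1 at 229 against 187 to 193 CPM (0.857), and control 2 had PALMD at 152 against 139 to 140 CPM (0.907).

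Activated fibroblast genes were higher in banded pigs while fibroblast identity markers moved apart. A larger share of fibroblasts in an unchanged state would raise both by about the same factor. However, 12 of 19 identity markers lay more than 2 SE below the median log2 fold change of the activation list, 0.71. That count cannot decide alone, as it was not made for the activation list, whose own members also lie on both sides of their median. Of the identity markers 3 were called higher by edgeR: PI16 (log2 fold change 2.13, adjusted p = 0.000315), THY1 (1.045, 0.00809) and VIM (0.57, 0.046). SCARA5 (-2.08, 0.0101), ABCA8 (-1.68, 0.0139) and, close to the threshold, PDGFRA (-0.49, 0.048) were called lower. These falls argue against a larger share as the whole cause, but they were not followed under the alternatives. A lower share of cardiomyocyte RNA would raise the markers of all other cell types alike. The endothelial score changed by -0.575 relative to the macrophage score (SE 0.221, exact two-sided permutation p = 0.0286, the smallest this design can give). The size rested on banded 2 (-0.381 without it, SE 0.125). The difference was within 2 SE without banded 1 (-0.59, SE 0.301) and had an exact p of 0.0571 without any 1 control. It cannot decide alone, as a rise of macrophage markers only would also give it. Taken singly, the macrophage score was higher in banded pigs (0.391, SE 0.187). The endothelial (-0.184, SE 0.0714), pericyte and smooth muscle (-0.0985, SE 0.108) and fibroblast identity (-0.0174, SE 0.0716) scores were not. Epicardial tissue in the banded pieces cannot be told apart from a change in fibroblasts: the score of its 7 markers was higher by 1.03 (SE 0.353, exact p = 0.0286), most of it in the keratins KRT18 (log2 fold change 3.70) and KRT8 (3.08, adjusted p = 0.0787), while ALDH1A2 fell, and UPK1B (1.53, 0.293), WT1 (0.872) and TBX18 (0.329) were not called. The edgeR call of ALDH1A2 (adjusted p = 0.021) was lost without control 2 (0.0515), control 3 (0.0583) or control 4 (0.0513). A change of state of fibroblasts with banding, with or without a larger share of them, remains a hypothesis.

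Banded 3 lay more than 2-fold beyond the other 7 libraries in 425 genes, against 41 to 200 in each of the others. Length-dependent bias would tie its deviation to gene length, but Spearman's rho across genes was -0.00017, against up to 0.143 in size elsewhere, and its 10 most counted genes took 31.9% of counts, against 36.8 to 43.6%. Handling before freezing cannot be told apart, as its immediate-early score of 0.592 was the highest of the banded libraries (-1.42 to -0.0383 in the others) but below the 0.831 of control 4, and its heat-shock score of 1.40 was the highest of all libraries (next 0.382). The shared change at a larger size would give a slope above 1.2, the bound set before, on the other banded libraries. The slope was 1.03, under that bound but above the 0.743 to 0.86 of banded 1, 2 and 4. Each slope used genes called without its own library, a choice that lowers slopes, so the bound cannot decide this. A difference in how far this animal's disease had gone was not tested.

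Controls 1 to 3 held far fewer ATP8 and ND1 counts than the other 5 libraries, while a gene model of 95 bases on chromosome 9 held far more. Lower mitochondrial RNA content would lower all 13 protein genes, but 3 of 13 (ND1, COX1 and ATP8) lay below the other 5 libraries, which argues against it. Reads placed on a nuclear copy are a candidate explanation: the lowest count of controls 1 to 3 was 140 times the highest of the others in that model, against 1.48 in the next of 239, although it held far fewer counts than ND1 lacked. A mitochondrial variant against the reference cannot be told apart from this, as 2 of 13 genes (ND1 and ATP8) lay more than 2-fold lower and counts per gene hold no bases. No biological explanation was tested, since the labels give no maternal line.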

How the results depend on the processing

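One alternative, without mitochondrial-genome genes and the model on chromosome 9, was chosen after seeing the data. All 954 genes kept their sign in each setting in which they were tested. DESeq2 called 1631 genes (840 higher, 791 lower), including 952 of the 954, and the cause was not tested. The test against a 1.5-fold change, a stricter question by construction, called 148 (79 and 69), and library size alone called 303 higher and 508 lower. Without 1 library, 399 to 962 genes were called, 201 to 499 higher and 198 to 476 lower, with one animal fewer. The lowest counts came without control 1 (399), control 3 (409) or control 2 (415). Camera called 8 of the 43 lists, and 5 to 13 without 1 library, not always the same lists. With an estimated correlation 0 lists were called, and fry called 1. With an absolute log2 fold change of at least 1 in both tables the overlap with the authors' deposited table was 88.2% of the calls here and 67.8% of theirs, and the cause was not tested. Of the 79 named genes called, 31 kept the call in all alternatives that tested them (CDH9, CP, GALNT14, KRT18, LYPD6B and WWC1 were not tested with the stricter filter on low counts), 13 lost it only against a 1.5-fold change and 35 in at least 1 other, none with the sign turned.

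The sign turned for 10 of the 30 uncalled genes. With library size alone, which moved the median log2 fold change of all genes by -0.10, the log2 fold change was -0.059 for CD74 (a gene model that also covers RPS14 exons), -0.028 for FABP3 and -0.076 for OXCT1, a turn by construction. It was 0.013 for SLC25A4 and 0.011 for SOD2 with 1 surrogate variable, and the cause of this and of the turns below was not tested. Without 1 library the log2 fold change was -0.294 to 0.137 for CCL5, -0.009 to 0.359 for CCND1, -0.031 to 0.118 for CD74, -0.161 to 0.248 for FABP3, -0.042 to 0.249 for GAPDH, -0.023 to 0.459 for IFI6, -0.134 to 0.034 for MDH2, -0.072 to 0.091 for OXCT1, -0.167 to 0.055 for SLC25A4 and -0.188 to 0.031 for SOD2. List directions turned with library size alone for sarcomere (adjusted p = 0.975), respiratory chain (0.701) and fibroblast identity genes (0.975), and for the last also without shared members (0.936). Without 1 library the direction turned at least once, with an adjusted p of 0.528 to 0.935 for sarcomere, 0.07 to 0.94 for respiratory chain, 0.174 to 0.654 for cytokine, 0.0358 to 0.749 for interferon, 0.343 to 0.912 for antigen-presentation, 2.61e-07 to 0.913 for mitochondrial-genome, 0.651 to 0.973 for fibroblast identity, 0.0637 to 0.507 for adipocyte, 0.754 to 0.94 for neutrophil and mast cell, 0.263 to 0.866 for erythroid, 0.663 to 0.922 for Schwann cell and 0.0412 to 0.917 for immediate-early genes. The mitochondrial-genome list was called, higher, without control 4, where all controls left held the low ATP8 and ND1 counts.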

Other observations

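The genes in this part lie outside the naming rule and were chosen after their values were seen, among genes called by edgeR's quasi-likelihood test (CPM as mean ± SD, 4 animals each). Several stood in no gene list. FSTL3, a secreted inhibitor of activins, was higher in banded pigs by 2.61 ± 0.17 on the log2 scale (SE, adjusted p = 2.61e-05). The Wnt ligand gene WNT2 rose from 0.471 ± 0.178 to 3.87 ± 1.35 CPM (adjusted p = 0.00164). S100A1, a calcium-binding protein gene of cardiomyocytes, rose from 120 ± 25.2 to 667 ± 305 CPM (adjusted p = 0.00169). IL34, a ligand of the macrophage growth factor receptor CSF1R, rose from 16.6 ± 1.01 to 46.8 ± 14.7 CPM (adjusted p = 0.00188). DHRS7C, a gene of the sarcoplasmic reticulum, fell from 136 ± 8.23 to 29.3 ± 8.46 CPM (log2 fold change -2.21 ± 0.19, adjusted p = 0.000184). CYP27A1, a sterol hydroxylase, fell from 71.6 ± 3.23 to 25.4 ± 5.02 CPM (adjusted p = 0.000354). MAOB, a monoamine oxidase, fell from 25.8 ± 6.88 to 6.05 ± 2.36 CPM (adjusted p = 0.00376).

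Other genes here were members of the lists described above. Among activated fibroblast genes, SFRP1 rose from 21.8 ± 5.78 to 98.8 ± 21.8 CPM (adjusted p = 0.000309). THBS4 rose from 116 ± 26.6 to 443 ± 89.5 CPM (adjusted p = 0.000482), and LTBP2 from 19.0 ± 6.68 to 76.8 ± 6.37 CPM (adjusted p = 0.000669). In the stretch and fetal program ACTA1, the skeletal alpha-actin gene, rose from 6125 ± 749 to 14930 ± 4638 CPM (adjusted p = 0.00688). Among adrenergic, angiotensin and endothelin signalling genes CORIN, the protease that activates natriuretic peptides, fell from 81.5 ± 16.5 to 33.7 ± 8.64 CPM (adjusted p = 0.00466). SCARA5, a ferritin receptor gene among the fibroblast identity markers, fell from 92.3 ± 29.1 to 21.9 ± 10.4 CPM (adjusted p = 0.0101). These genes were not followed one by one under the alternatives.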
